A study of Mus musculus with 6 samples.

How the data were processed

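Native chromatin immunoprecipitation and sequencing had been carried out on CD8+ tumour-infiltrating lymphocytes from wild-type mice and from mice in which Cre recombinase had deleted Atg5. Per the labels' protocols, lysed cells were digested with micrococcal nuclease, the digested chromatin was cleared with beads alone, and the remainder was incubated with antibody-bead complexes before Illumina adaptors were ligated. The series lists 6 samples, which are H3K4me3, H3K27me3 and input for each genotype. Peak lists of the 2 H3K4me3 libraries were used. The H3K27me3 and input samples were not analysed here.

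Peaks were called with MACS2 on the GRCm38 (mm10) build, per the submitters' processing notes. The MACS2 version and settings, the aligner, the read filters and any use of the input library are not given in the sources used here. Each list was called on 1 library and no replicates were pooled, as far as the peak names in the files show. The deposited lists give the start and end of each region and the position of its summit. The deposited fold values are ratios of the reads at the summit to the local background of the same library. The deposited −log10 p and −log10 q values refer to the same summit, and the lowest deposited −log10 q was 2.00 in the wild-type list and 2.02 in the knockout list. The deposited score is the −log10 q multiplied by 10 and written as a whole number, and it was not used. All of these values are the authors' own, they were not scaled between libraries, and in the report they were used only to describe, rank or filter regions within 1 list. Summit reads recovered from them, described further on, were scaled to the background of each library and compared in the closing section. Differences between the lists in the report therefore rest on where regions were called and how long they were. Such lengths depend on the depth of each library and on the calling threshold.

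No interval occurred more than once in a list. Regions on chromosomes 1 to 19, X and Y were kept. Regions on the mitochondrial genome and on unplaced scaffolds were counted apart. Regions were called shared if they overlapped by at least 1 bp (bedtools 2.31.1). Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

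Gene positions came from a RefSeq gene table of the same build (GRCm38.p6) with 21887 protein-coding genes on the chromosomes kept. That table gives gene starts and ends but neither strand, exons nor single transcript starts. The planned window around the 5′ end of each gene was therefore placed on the gene boundary with more covered length within 2.5 kb, summed over both lists, with ties going to the lower coordinate. This replacement was made after the gene table was seen. This choice treats both genotypes alike, but for some genes the boundary is the 3′ end or lies in a neighbouring gene. A start inside the annotated gene is missed. Windows on every annotated transcript start, and a split into exons and introns, could not be made from that table. A gene was called marked if a region overlapped the 1 kb on either side of its boundary. The covered length was the number of bp under regions within 2.5 kb on either side, with a maximum of 5001 bp.

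Gene lists, the genes to be named and all settings but those said to be added were fixed before the data were examined. The 21 lists held 396 distinct protein-coding genes. Zfp683 and Mx1 were left out because the gene table holds them as pseudogenes. For each list the median difference in covered length, knockout minus wild type, was placed among 10000 random lists of the same size, drawn from 20 bins of the mean covered length of both lists. The text names a fixed set of 25 genes, the 10 genes marked in 1 list only with the highest fold in it (for each list), the 10 with the longest gain and the 10 with the longest loss of covered length, and up to 4 members of each gene list with the largest difference. Predicted genes were passed over when ranking by fold or by gain and loss. Some genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

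Each genotype has 1 library, so no test between genotypes was possible and no p-value is given. Genes are not replicates, and the percentiles only describe these 2 libraries. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. The lists do not state the depth of either library. With fold = (reads + 1)/(background + 1) and a Poisson p, a whole number of reads at the summit was recovered within 0.001 of the deposited −log10 p for 48012 of 48014 wild-type regions and 45835 of 45836 knockout regions with a −log10 p under 250. This step was added after the data were seen, and its values appear only here and in the closing section. The genome-wide background was 2.85 reads in the wild-type library and 2.62 in the knockout library, and the lowest summit held 10 reads in each.

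The steps were tested on simulated data. All of 500 simulated windows gave the right covered length. For the gene lists, the mean covered lengths of the 21887 genes were kept and the differences were drawn from a normal distribution. Of 10 simulated lists of 20 genes shifted by 300 bp, 7 lay above the central 95% of random lists. Of 100 unshifted lists, 3 lay outside it on either side. These counts do not measure error rates on the real differences. Alternatives were a −log10 q of at least 5 or 10, the 20000 regions with the highest −log10 q in each list, other overlaps, windows, gaps and widths, and unmatched random lists. A fold of at least 5, either gene boundary and the whole gene body were added after the data were seen.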

Results

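H3K4me3, a histone mark found at the starts of active genes, was profiled in CD8+ tumour-infiltrating lymphocytes taken from E0771 tumours in C57BL/6 mice. E0771 is a mouse mammary tumour line of the same strain. Cells came from wild-type mice or from mice lacking Atg5, which encodes a protein needed to build autophagosomes. Each genotype had 1 library, so the differences below have no replicate check. The wild-type list held 48546 regions on the main chromosomes and the knockout list 46565. These covered 71.3 and 73.1 Mb, with median widths of 1103 and 1130 bp. The depth of the libraries is not stated in the lists.

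The deleted gene and its pathway were examined first. The Atg5 boundary (chromosome 10, 44268322) was marked in both lists, with 2926 bp covered in the wild type and 2705 bp in the knockout. The labels do not say which part of Atg5 was deleted, so this region does not check the labels. Of the 31 autophagy genes, 29 were marked in each list. Their covered length was longer in the knockout for 18 and shorter for 12, with a median difference of 52 bp at percentile 90.2 of the matched random lists and 99.75 of unmatched ones. Rb1cc1, a subunit of the kinase complex that starts autophagy, had 1148 bp more in the knockout. Atg3, which lipidates the LC3 proteins, had 507 bp more, and the mitophagy receptor gene Bnip3l had 566 bp more. Pik3c3, the class III PI3-kinase, had 1454 bp within 2.5 kb of its boundary in the knockout and 0 bp in the wild type, but no region within 1 kb in either list.

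Genes that define T cells differed most between the lists. All 20 T cell identity genes were marked in the knockout list, whereas 8 of 20 were marked in the wild-type list (40.0%, 95% interval 19.1 to 63.9%). Covered length was longer in the knockout for 19 of 20, with a median difference of 3685 bp (percentile 100). Cd8a, the alpha chain of the CD8 co-receptor (chromosome 6, 71373427 to 71379171), lay under a knockout region of 6461 bp with an authors' fold of 21.0, and had 4386 bp against 0 bp covered. The transcription factor Bcl11b had 4913 bp against 0 bp, and Cd2, an adhesion molecule of T cells, had 4553 bp against 0 bp. The Cd2 boundary used is its end of lower coordinate, which may not be the 5′ end. Lck, the kinase that starts T cell receptor signalling, had 4953 bp against 327 bp. Cd3e, a chain of the CD3 complex, had 3615 bp against 0 bp. Gata3 was the exception, with 1919 bp in the knockout and 1926 bp in the wild type. The T cell genes Cd3e and Gata3 are named here after their values were seen. The list lay above the central 95% of its random lists in all 8 settings tried.

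**Figure D1:**
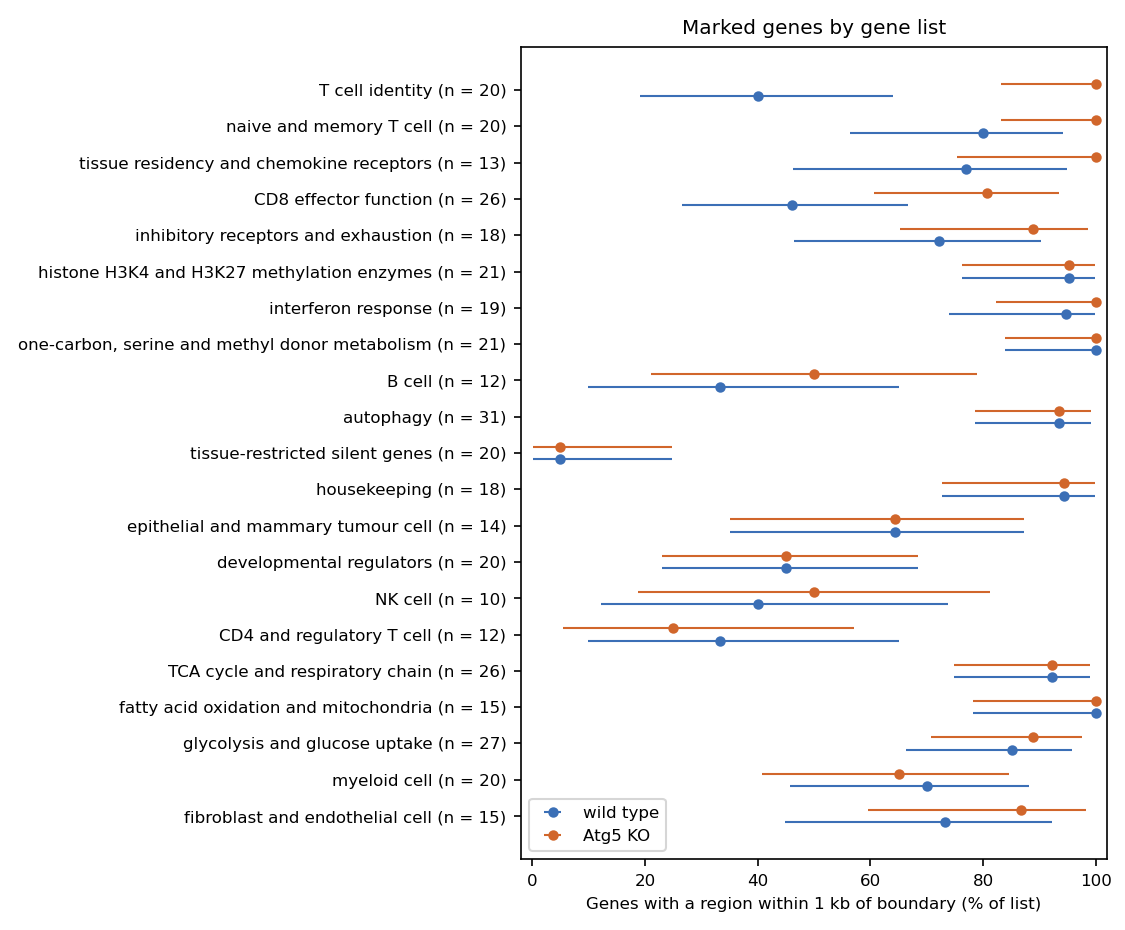
Share of the genes of each list (%) with an H3K4me3 region within 1 kb of the gene boundary in the wild-type list (blue) and the Atg5 knockout list (orange), 1 library each, where bars are exact 95% intervals covering counting error only and n is the number of genes. T cell identity genes were marked at 40.0% in the wild type and 100% in the knockout, while housekeeping, autophagy and one-carbon genes had equal shares.

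Genes of CD8 effector function were marked more often in the knockout list. Of 26 genes, 21 were marked in the knockout (95% interval 60.6 to 93.4%) and 12 in the wild type (26.6 to 66.6%), and no gene was marked in the wild type only. Covered length was longer in the knockout for 17 and shorter for 5, with a median difference of 1190 bp (percentile 100). Ifng, the gene of interferon gamma (chromosome 10, 118441046 to 118445894), had 2047 bp against 0 bp, under regions with a fold of at most 5.01 within 1 kb. The granule genes Gzmb and Prf1 had 2173 and 2408 bp against 0 bp, and Nkg7, a granule membrane protein of killer cells, had 4184 bp against 0 bp. Il2ra, a chain of the interleukin receptor that T cells raise on activation, had 2771 bp against 0 bp. Tnf had 3674 bp against 2511 bp. The transcription factors Tbx21 and Eomes, which direct effector differentiation, had 3076 against 974 bp and 4380 against 1231 bp. These differences moved with the T cell identity genes, whose median difference was 3685 bp. With 20000 regions kept in each list, the effector median was 0 bp, at percentile 49.985 of its random lists, with 10 longer and 2 shorter.

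Genes of naive and memory T cells showed the same direction. All 20 were marked in the knockout and 16 in the wild type, 18 were longer in the knockout and 1 was shorter, and the median difference was 1637 bp (percentile 100). Tcf7, the transcription factor TCF-1 of naive and stem-like T cells, had 4605 bp against 2708 bp, and its knockout region spanned 22317 bp. The cytokine receptor gene Il7r had 3792 bp against 1484 bp, and the chemokine receptor gene Ccr7 had 4055 bp against 899 bp. For Ccr7 the boundary used is the end of lower coordinate, which may not be the 5′ end. Dapl1, Satb1 and Slamf6 had 3729, 3527 and 3333 bp more in the knockout. Both the effector and the memory list were longer in the knockout, together with the T cell identity list (median 3685 bp).

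Inhibitory receptor and exhaustion genes were longer in the knockout for 12 of 18 and shorter for 4, with a median of 518 bp (percentile 99.99). Pdcd1, which encodes the checkpoint receptor PD-1, had 3067 bp against 844 bp. Tox, a transcription factor of exhausted T cells, had 2762 bp against 1204 bp. The checkpoint receptor genes Ctla4 and Btla had 2613 and 2808 bp more in the knockout, and Irf4 had 2187 bp more. Havcr2 (TIM-3) had 1681 bp against 1165 bp and Lag3 had 1447 bp against 1569 bp. The Lag3 boundary used is its end of lower coordinate, and the gene table does not show whether this is the 5′ end. With 20000 regions per list, the median was 51 bp at percentile 94.8. Of 13 residency and chemokine receptor genes, 11 were longer in the knockout and 2 were shorter, with a median of 1313 bp (percentile 100). Cxcr6, Ccr2, Itgae and Rgs1 had 4532, 3867, 2711 and 2395 bp more. T cell identity genes differed along with both lists (median 3685 bp).

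**Figure D2:**
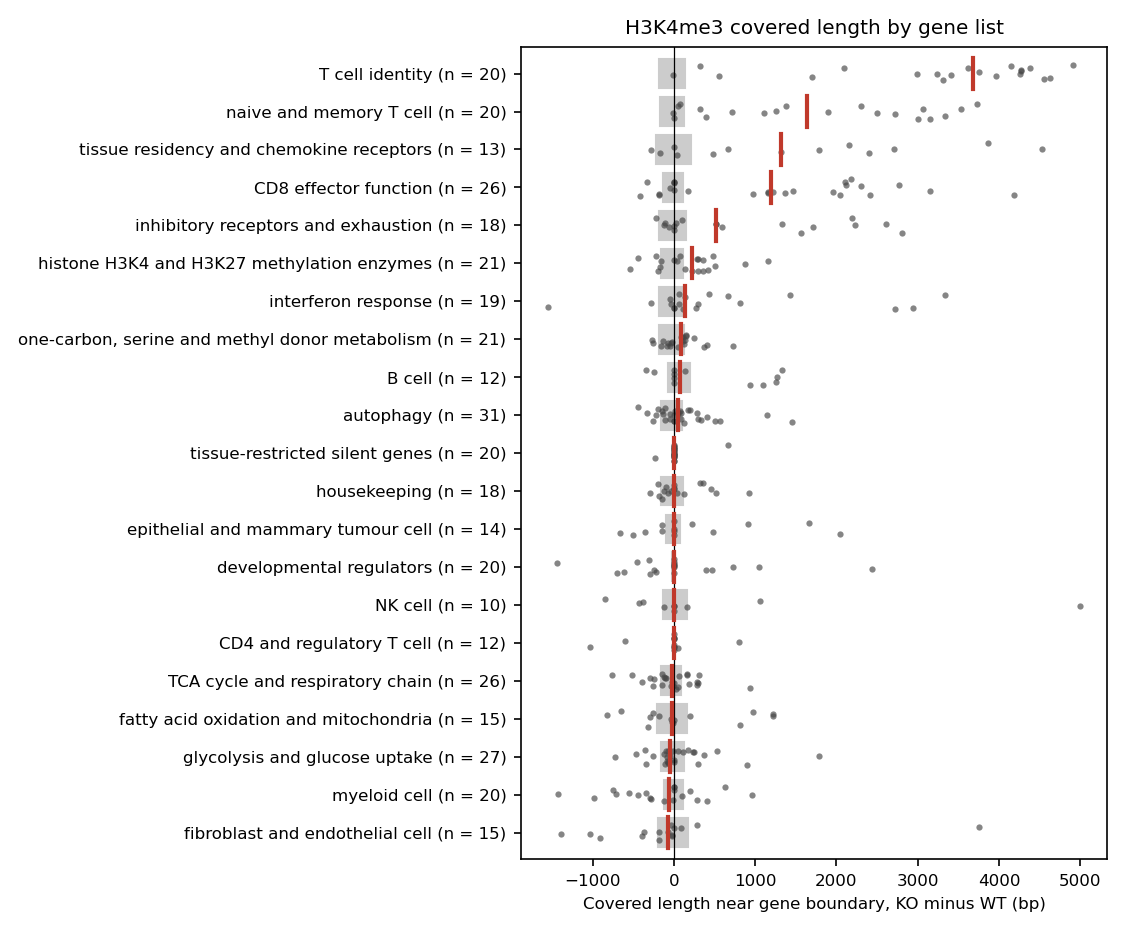
Difference in H3K4me3 covered length within 2.5 kb of the gene boundary (bp, knockout minus wild type, 1 library each), where each point is a gene, red bars are list medians and grey boxes are the central 95% of 10000 matched random lists. The medians of the T cell lists lie to the right of their boxes, at 3685 bp for T cell identity, whereas the glycolysis median is −53 bp (0 bp within 1 kb).

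The metabolic lists lay within the central 95% of their matched random lists. Among unmatched random lists, glycolysis lay below it (percentile 2.17) and one-carbon genes above it (percentile 99.5). Among 27 genes of glycolysis and glucose uptake, 24 were marked in the knockout and 23 in the wild type, 11 were longer and 15 shorter in the knockout, and the median difference was −53 bp (percentile 30.0). The majority turned round within 1 kb, with 9 longer and 6 shorter, and over the gene body, with 14 longer and 13 shorter. Slc2a1, the glucose transporter GLUT1, had 3384 bp against 3738 bp. Hk2, which phosphorylates glucose, had 3638 bp against 3717 bp, and the pyruvate kinase gene Pkm was covered over 5001 bp, the whole window, in both. Ldha, lactate dehydrogenase, had 906 bp against 1011 bp, with no region within 1 kb of its boundary in either list. The largest difference was 1784 bp more in the knockout at Aldoa, whose boundary lies within 5 kb of Ppp4c. The only knockout region within 1 kb of that boundary lay outside the gene. Pdk1 and Ldhb had 899 and 528 bp more in the knockout, while Hif1a had 1221 bp against 1944 bp. The 26 genes of the TCA cycle and respiratory chain had a median of −20 bp (percentile 55.0), with Sdha at 938 bp and Sucla2 at −757 bp. The 15 genes of fatty acid oxidation had a median of −23 bp (percentile 54.1), where Hadha and Hadhb share 1 boundary region with 1214 bp more. The 21 one-carbon and methyl donor genes were all marked in both lists, with a median of 88 bp (percentile 93.5). Mat2a, which makes S-adenosylmethionine, had 3964 bp against 4048 bp, and Mthfd2 had 729 bp more in the knockout.

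Histone methylation enzymes were longer in the knockout for 14 of 21 and shorter for 6, with a median of 226 bp (percentile 99.8). The H3K4 methyltransferase genes Kmt2d and Kmt2a had 1157 and 869 bp more, the H3K27 methyltransferase gene Ezh2 had 512 bp more, and Cxxc1 had 2333 bp against 2871 bp. The Kmt2d boundary used is its end of lower coordinate and lies within 5 kb of Prkag1. The gene table does not show whether this is the 5′ end, so the 1157 bp may belong to Prkag1. T cell identity genes were longer in the same library (median 3685 bp). The enzyme list lay above the central 95% of its random lists in 5 of 8 settings, and not within 1 kb (median 0 bp), within 5 kb (percentile 96.3) or over the gene body (percentile 92.1). Interferon response genes were longer for 13 of 19 and shorter for 4, with a median of 142 bp (percentile 97.1), beside the 3685 bp of the T cell identity genes. This list lay above the central 95% of its random lists in 5 of 8 settings. Gbp4, Ifi47 and Irf8 had 3338, 2947 and 2726 bp more in the knockout, and Oas1a had 2094 against 3647 bp.

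Markers of other cells were covered in both lists. Of 14 epithelial and mammary tumour genes, 9 were marked in each list, and the median difference was 0 bp (percentile 54.8). Krt8, a keratin of simple epithelia, had 3670 bp in the wild type and 3311 bp in the knockout, under regions with folds of 23.0 and 26.8 in their own lists. Esrp1, Cldn7 and Epcam had 2044, 1664 and 908 bp more in the knockout, while Ehf had 565 against 1223 bp. Of 20 myeloid genes, 14 were marked in the wild type and 13 in the knockout, with 6 longer and 11 shorter in the knockout and a median of −65.5 bp (percentile 9.30). At a −log10 q of at least 5 this median was −152.5 bp (percentile 0.49), and over the gene body it was −309 bp (percentile 0.78). It was 0 bp at a −log10 q of at least 10, with equal list lengths and within 1 kb, where 7 genes were longer and 4 shorter. Csf1r, the macrophage growth factor receptor, had 1610 bp against 2047 bp. Clec7a had 609 against 2037 bp, Itgax 632 against 1620 bp, and Spi1 3517 against 2558 bp. Fibroblast and endothelial genes were shorter in the knockout for 11 of 15 and longer for 3, with a median of −75 bp (percentile 21.0). Pecam1 of endothelial cells had 2202 against 3589 bp, Pdgfrb 3621 against 4654 bp and Col3a1 3323 against 4236 bp. Thy1, which T cells also use, had 3755 against 0 bp in this list.

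Among 12 genes of CD4 and regulatory T cells, 4 were marked in the wild type and 3 in the knockout. Cd4 had 1309 bp in the knockout against 1913 bp, and Foxp3 was not covered in either list. The Cd4 boundary used is its end of lower coordinate and lies within 5 kb of Gpr162. The gene table does not show whether this is the 5′ end. Of 12 B cell genes, 6 were longer in the knockout and 2 were shorter, with a median of 70 bp (percentile 91.8). Ebf1 and Cd79b had 1326 and 1265 bp more. Among 10 NK cell genes, 3 were longer and 4 were shorter, with Klrk1 at 5001 against 0 bp. Housekeeping genes had a median difference of 0 bp (percentile 63.6), with 17 of 18 marked in each list, 7 longer and 8 shorter in the knockout. Within 5 kb, 14 of these genes were longer and 3 shorter (median 355 bp, percentile 97.4). Developmental regulators had a median of 0 bp with 9 of 20 marked in each list, 6 of them in both. The other marked regulators were 3 in the wild type only and 3 in the knockout only. Of the tissue-restricted genes 1 of 20 was marked in each list (Apoa2). The Apoa2 boundary lies within 5 kb of Nr1i3 and Tomm40l. In total 6 of the 21 lists lay outside the central 95% of their random lists, all above it. Chance alone puts about 1 list in 20 there, where the random medians vary. For the CD4 and regulatory and the tissue-restricted lists, the central 95% of random medians ran from 0 to 0 bp. Genes without coverage were matched only to genes without coverage, so these lists could hardly fall outside.

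**Figure D3:**
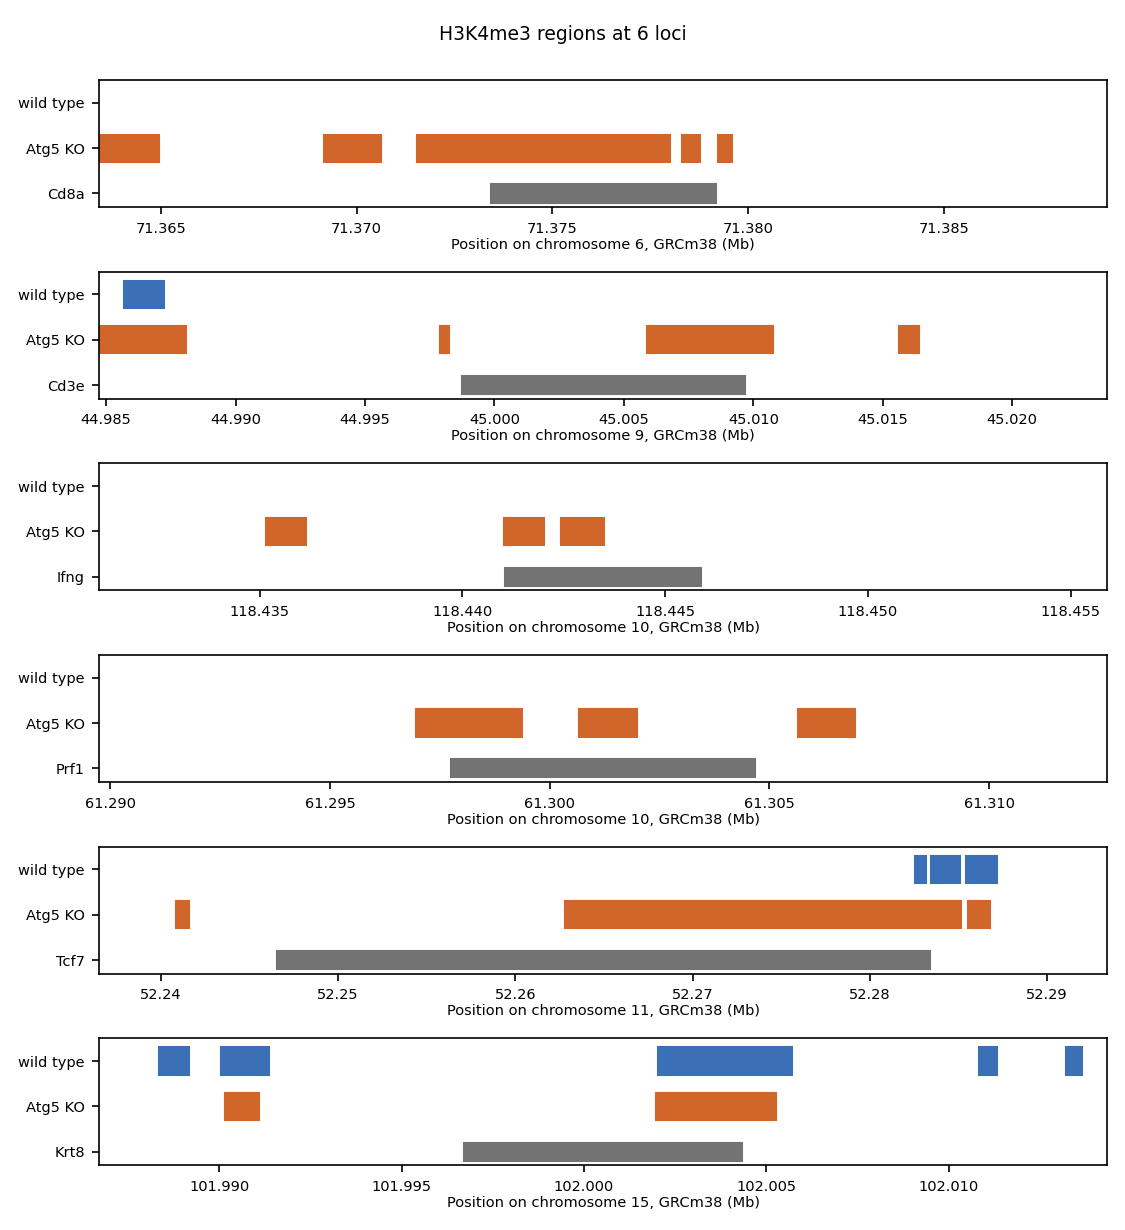
Positions (Mb, GRCm38) of H3K4me3 regions in the wild-type list (blue) and the Atg5 knockout list (orange) around 6 genes (grey bars, gene start to end). At Cd8a, Ifng and Prf1 only the knockout has regions within the window drawn, at Tcf7 the knockout region is 22317 bp wide, and at Krt8 both lists have a region at the gene boundary.

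Across the genome, 73.3% of wild-type regions (95% interval 72.9 to 73.6%) overlapped a knockout region, and 75.97% of knockout regions (75.6 to 76.4%) overlapped a wild-type region. Merged together the lists gave 58414 regions, of which 34243 were in both, 12983 in the wild type only and 11188 in the knockout only. Regions in 1 list were weaker within that list, with median folds of 4.42 against 12.0 for shared regions in the wild type and 4.98 against 10.5 in the knockout. Regions within 1 kb of a protein-coding gene boundary made up 24.7% of the wild-type list and 26.1% of the knockout list. A further 34.6% and 37.6% lay elsewhere in a gene, and 40.7% and 36.3% lay outside protein-coding genes.

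Of 21887 protein-coding genes, 12700 were marked in both lists, 720 in the knockout only and 419 in the wild type only. Over the gene body and 1 kb around it these numbers were 506 and 556. Of the 720, 559 had no wild-type coverage within 2.5 kb, and of the 419, 299 had no knockout coverage there. Genes marked in the knockout only with the highest fold were Igflr1, Prm3, Fbxl22, Ifi47, Metrn, Hlcs, Aldoa, Ikzf1, Tmem191c and Trpm5, with folds from 52.5 for Igflr1 to 26.8 for Trpm5. All of these but Ifi47 also had wild-type coverage within 2.5 kb. Ikzf1, the lymphoid transcription factor Ikaros, lay in a knockout region of 13288 bp. The boundaries of Prm3, Igflr1, Fbxl22 and Aldoa lie within 5 kb of Socs1, Kmt2b, Usp3 and Ppp4c, in that order. Genes marked in the wild type only with the highest fold were Commd1, Pkd1l2, Rd3, Tymp, Gsdme, Panx2, Gpr61, Bst1, Wfikkn1 and Foxl1, with folds from 40.6 for Commd1 to 32.8 for Foxl1. All of them had at least 1150 bp of knockout coverage within 2.5 kb.

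Over the 14846 genes with any coverage, covered length was longer in the knockout for 6773 and shorter for 7915, and the median difference was −24 bp. Gains of at least 2000 bp were seen at 251 genes and losses of at least 2000 bp at 15. The 10 largest gains were Gimap7, Klrk1, Bcl11b, Skap1, Fam189b, Lck, Ubash3a, Cd2, Eif2d and Cxcr6, from 5001 bp for Gimap7 to 4532 bp for Cxcr6. Gimap7 belongs to a family of lymphocyte GTPases, and Skap1 and Ubash3a act in T cell receptor signalling. The boundary used for Eif2d lies inside Rassf5. The largest losses included Dok7, Tmem204, Dsc3, Tie1, Lrrc25, Dnajc5b, Exoc3l2 and Prkch, where Dok7 fell by 3024 bp and Prkch by 2177 bp. The Prkch boundary used is the end of higher coordinate, and at its other end the knockout had a domain of 30338 bp with 15.9% covered in the wild type. Tie1 is an endothelial receptor kinase (0 bp in the knockout, 2260 bp in the wild type), and Dsc3 is a desmosomal cadherin of epithelia (826 against 3376 bp). For Tie1 and Dsc3 the boundary used is the end of lower coordinate, which may not be the 5′ end.

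Broad domains were formed by joining regions over gaps of up to 1 kb. The widest 5% were 2216 wild-type domains of at least 4312 bp and 2106 knockout domains of at least 4848 bp. Of these, 57.8% of the wild-type domains (55.7 to 59.9%) overlapped a widest domain of the knockout, and 60.1% of the knockout domains (58.0 to 62.2%) overlapped one of the wild type. Every widest wild-type domain met some knockout region, whereas 125 of the knockout domains met no wild-type region. The widest knockout domain spanned 56761 bp at the T cell receptor alpha locus (chromosome 14, 54172627 to 54229387), of which wild-type regions covered 8.43%. Genes at the following domains were chosen by width after the values were seen. The next domain spanned 55361 bp at Ptprc, the leukocyte antigen CD45, with 18.98% covered in the wild type. Ets1 lay in a knockout domain of 44811 bp (47.7% covered), Satb1 in 33021 bp (3.73%) and Ms4a4b in 28383 bp (7.51%). Coverage by wild-type regions was higher at some other wide knockout domains, with 75.2% of 38177 bp at a cluster of 5S ribosomal RNA genes and 80.5% of 31916 bp at Chd2. The 3 widest wild-type domains lay in the same cluster, spanned 33697, 25949 and 24287 bp, and were covered to 72.2%, 68.1% and 69.6% in the knockout. Further wide wild-type domains lay at Plec (19834 bp), Rara (16890 bp) and Lmna (16376 bp), and knockout regions covered 96.4%, 86.1% and 83.6% of them. Of 97 genes in the 5 T cell lists, 47 lay within 2.5 kb of a widest knockout domain and 14 of a widest wild-type domain. For 137 housekeeping, metabolic and autophagy genes these numbers were 30 and 33.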

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

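The tests in this part were all chosen after the result was seen. Regions outside the main chromosomes took part in no comparison. The wild-type list held 63 regions on unplaced or unlocalised scaffolds and the knockout list 60. The knockout list held 4 regions on the mitochondrial genome and the wild-type list 2, and no difference is read from these numbers.

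The pattern that bears most on the comparison is that Cd8a, Cd3e, Cd2, Lck and Bcl11b were not marked in the wild-type library, although its cells are labelled CD8+ lymphocytes, a selection that would remove other cell types (Cd3e was named after its value was seen). Lower sensitivity of the wild-type list as the whole cause is argued against by 4057 genes outside the T cell lists whose knockout regions had folds in the range of the identity genes (12.7 to 30.7), since 97.9% of them (97.4 to 98.3%) were marked in the wild type, as against 40.0% of identity genes (19.1 to 63.9%). A smaller loss of enrichment stays open, with a median log2 ratio of summit reads, knockout to wild type, of 0.22 over all genes and 0.34 over housekeeping genes. A smaller share of T cells in the wild-type library cannot be told apart from other causes. Of the 49 myeloid, epithelial and stromal markers, 69.4% were marked there and 71.4% in the knockout. These include Thy1, also a T cell identity gene, which was marked in the knockout only. Developmental regulators were marked at 9 of 20 in each list, of which 6 were marked in both, 3 in the wild type only and 3 in the knockout only. The summit ratios of the 3 marker lists (0.12, 0.24 and −0.40) did not all lie below that of all genes. The upper quartile lay below it for fibroblast and endothelial genes (−0.096), but not for myeloid (0.62) or epithelial genes (0.74). A mislabelled library cannot be told apart, since the Atg5 boundary was covered in both lists (2705 bp in the knockout) and a swap leaves no trace there, and an effect of the genotype also stays open because genotype and library coincide.

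The second pattern is the width of the largest domains. The 99th percentile of region width was 5703 bp in the wild type and 6865 bp in the knockout. A longer fragment size in peak calling for the knockout is argued against by the difference of 1162 bp at that percentile, as against 14 bp between the narrowest regions (295 and 281 bp). A smaller share of T cells in the wild-type library stays open: 47 genes of the T cell lists lay near the widest knockout domains and 14 near the widest wild-type domains (30 and 33 for housekeeping, metabolic and autophagy genes), which an effect of the genotype on T cell genes would give as well.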

How the results depend on the processing

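Settings on fold, either gene boundary and the gene body were chosen after the results were seen. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The alternative on annotated transcript starts was not run. Of 235 values under an alternative, 174 stayed within the counting interval or within 1.5 times of the main count, and 61 moved. Of the 6 lists outside their random lists, 0 had their majority of longer or shorter genes turn round in any of the 8 settings. Of the 15 other lists 7 did: myeloid, one-carbon, fatty acid, glycolysis and housekeeping genes within 1 kb, NK cell and housekeeping genes within 5 kb, glycolysis, TCA cycle, NK cell and housekeeping genes over the gene body, and NK cell genes at a −log10 q of at least 10. Genes marked in 1 list only were more numerous in the knockout in every setting but the gene body with 1 kb around it (506 against 556). What depth limits was not tested, since the depth of the libraries is not stated in the lists. The T cell identity, naive and memory, and residency lists lay above the central 95% of random lists in all 8 settings of threshold and window, the effector and the exhaustion list in 7, histone enzymes and interferon genes in 5 each, and B cell genes in 1 (gene body). Myeloid genes lay below it at a −log10 q of at least 5 (percentile 0.49) and over the gene body (0.78), but not in the other 6 settings. The cause of the moves below was not tested, except that stricter lists hold fewer regions. Shared wild-type and knockout regions were 57.1% and 59.5% with reciprocal overlap of 50%, 51.1% and 53.3% with summits within 200 bp, 76.8% and 78.0% at a −log10 q of at least 10, 80.7% and 80.4% with equal list lengths, and 77.0% and 77.2% at a fold of at least 5, and the wild-type share was 76.3% at a −log10 q of at least 5. Merged regions in the wild type only were 7445 at a −log10 q of at least 10, 3866 with equal lengths and 7900 at a fold of at least 5. Those in the knockout only were 6958 at a −log10 q of at least 10 and 3912 with equal lengths, and those in both were 15944 with equal lengths. Marked genes with equal lengths were 257 in the wild type only and 1149 in the knockout only. Genes longer in the knockout were 33.9% in a window of 1 kb, 46.7% in 5 kb and 47.4% over the gene body, against 45.6%. Unmatched random lists put 10 lists outside, against 6, where one-carbon (percentile 99.5), autophagy (99.75) and interferon genes (99.83) were added above and glycolysis (2.17) below. With the gene body, longer members were 84.6% of effector, 88.9% of exhaustion, 100% of identity and 83.3% of housekeeping genes. With equal lengths they were 38.5% of effector, 100% of identity, 7.14% of epithelial and 0% of developmental genes, and identity genes were also at 100% at a −log10 q of at least 5 or 10 and at a fold of at least 5. In a window of 1 kb they were 15.4% of TCA cycle, 23.8% of one-carbon, 29.0% of autophagy, 33.3% of histone enzyme, 36.8% of interferon and 0% of CD4 and regulatory genes, and in 5 kb 77.8% of housekeeping genes. Members of equal covered length do not count as longer in these shares. Within 1 kb, longer and shorter members were 9 and 8 for autophagy, 7 and 4 for histone enzymes and 7 and 5 for interferon genes. They were 4 and 10 for TCA cycle, 5 and 7 for one-carbon and 0 and 2 for CD4 and regulatory genes. Regions near a gene boundary (wild type, knockout) were 27.4% and 28.6% within 2 kb, 27.6% and 28.6% at a −log10 q of at least 5, 33.5% and 36.0% at 10, 47.6% and 51.7% with equal lengths, and 31.9% and 33.7% at a fold of at least 5. Overlap of the widest domains (wild type, knockout) was 50.6% and 53.9% with a joining gap of 3 kb, 54.3% and 55.1% at a −log10 q of at least 10, 50.6% and 50.4% with equal lengths, and 55.7% and 56.0% at a fold of at least 5. It was 72.5% of wild-type domains of at least 4 kb, and 57.8% of knockout domains at a −log10 q of at least 5.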

Other observations

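The values in this part were all chosen after the data were seen. The T cell receptor loci, which are assembled from gene segments and are not protein-coding genes in the table, carried long H3K4me3 domains in the knockout list. The joining and constant segments of the beta chain (chromosome 6, 41533864 to 41548181) were covered over 13376 of 14318 bp in the knockout and 0 bp in the wild type. Those of the alpha and delta chains (chromosome 14, 54123138 to 54224198) were covered over 51394 bp in the knockout and 2162 bp in the wild type. The gamma chain segments had 2633 against 759 bp. The immunoglobulin heavy chain joining segments and Ighm had 7519 against 450 bp, and the kappa segments had 0 bp in both lists.

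Reads recovered at the summits gave the height of regions near genes marked in both lists, scaled to the background of each library. Over 11689 genes the median log2 ratio of knockout to wild type was 0.22. It was 2.11 for the 8 T cell identity genes, 1.51 for 15 naive and memory genes, 0.66 for 11 effector genes, 1.29 for 9 residency genes, 0.24 for 13 inhibitory receptor and exhaustion genes, 0.20 for 21 glycolysis genes, 0.34 for 15 housekeeping genes, 0.12 for 13 myeloid genes, 0.24 for 9 epithelial genes and −0.40 for 11 fibroblast and endothelial genes. Genes with no wild-type region drop out of these medians. With such genes set to 10 reads, the lowest summit of each list, the median was 2.82 for 20 identity genes, 1.62 for 19 naive and memory genes, 1.12 for 20 effector genes, 1.51 for 12 residency genes and 0.71 for 16 inhibitory receptor and exhaustion genes. Il7r had 88 reads in the knockout against 21 in the wild type (ratio 4.55, 95% counting interval 2.805 to 7.72), Eomes 70 against 13 (5.85, 3.21 to 11.5) and Tnf 87 against 33 (2.87, 1.90 to 4.42). Tcf7 had 88 against 100 (0.956, 0.710 to 1.29), although its covered length was longer in the knockout. Slc2a1 had 133 against 116 (1.25, 0.964 to 1.61) and Krt8 had 96 against 129 (0.809, 0.614 to 1.06). These intervals cover counting error only, and the ratios have no replicate check.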
